A study of Mus musculus with 36 samples.

How the data were processed

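Liver RNA was measured by stranded mRNA sequencing in 36 C57BL/6 mice, 18 wild type and 18 with a prenatal knockout of Bmal1, the gene listed under its symbol Arntl. Mice lived under 12 h of light and 12 h of dark with free access to food. Livers were taken every 4 h at 6 Zeitgeber times (ZT, hours after lights on), from 3 mice per genotype and time. Per the labels, libraries were amplified with 13 PCR cycles, and 6 barcoded samples were pooled for sequencing on an Illumina HiSeq instrument; the labels do not say which samples shared a pool.

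The authors' processing notes name CASAVA, STAR 2.4.0f1 and the mm9 mouse genome; the program that counted reads, its annotation and its filters are not stated. The deposited table holds counts, as whole-number reads per gene on the sense strand, in the minimum form of the count that the file is marked with. It lists 21654 genes, none of them at 0 in all 36 libraries. Total counts lie between 12657858 and 12839653 per library (median 12744399), and the highest is 1.44% above the lowest. Totals this close point to a step that set a common depth, which the notes do not state. Every low whole number occurs, which counts scaled up and rounded would not give; this does not exclude scaling down. Over the 36 pairs of replicates, the variance between 2 libraries of a group was 11.3 to 234 times that of Poisson counts, so the spread between replicates, whatever its source, was larger than counting error in each pair. The pairs include mice of unlike sex, and sex was not separated in this range. Coordinates are those of the table, on mm9.

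Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr on the 12 genotype-by-time groups (minimum count 10, minimum total count 15), which left 13201 genes tested and 8453 not tested. TMM factors scaled the libraries. Quasi-likelihood fits had 1 mean per group and labelled sex as a covariate, since sex by label is balanced between genotypes at each time but not between times. The labels also give the cage of each mouse, 20 cages in all, and cage was used in no fit. F tests compared knockout with wild type over the mean of the 6 times and at each time, and the equality of the 6 differences on 5 degrees of freedom. A cosinor fit with genotype, sex and, per genotype, 2 terms of a 24 h period tested the rhythm in each genotype and whether the 2 terms differed; peak times and peak-to-trough folds come from it. With 6 times over 1 day, it cannot tell a 24 h rhythm from any other difference between times that has a similar course. A fit with sex within each genotype compared females with males, 9 of each per genotype by label, and tested whether the difference changed with genotype. Adjusted p values are Benjamini-Hochberg values over the 13201 genes, called under 0.05. Every adjusted p of a gene comes from edgeR unless DESeq2 is named. CPM values use TMM-scaled totals and are given as mean ± SD over libraries. Log2 fold changes are given ± the standard error from the F statistic.

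There were 27 gene lists, of which 26 had 5 or more tested genes. They were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the 26 lists, with an estimated correlation and fry as alternatives. Of the list members, 8 were not analysed here, since the table has no such symbol: Hmgcs1, Psmb9, Ly6g, Hbb-bt, Hbb-bs, Ahsp, Prss1 and Amy2a5. The clock lists overlap: 18 of the 20 core clock genes, 14 of the 16 E-box targets and 8 of the 9 REV-ERB-repressed genes also stand in another list, and no cell type marker does except 1 of the 10 for adipocytes.

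The comparisons, their tests, the lists and the rule for named genes were chosen before the data were examined. The rule takes Arntl and the core clock list; the 10 highest and 10 lowest fold changes over all times among called genes with a mean log2 CPM of at least 1 and 1 direction at all 6 times; up to 4 genes per list by smallest p; 3 highest and 3 lowest at each time and the 10 largest amplitudes per genotype, among called genes with the same minimum of log2 CPM; the 10 smallest p for the interaction; the 10 smallest p for a differing rhythm; 5 highest and 5 lowest per sex comparison, the 10 smallest p of its interaction, and the members of both sex-biased lists. Predicted genes, clones and pseudogenes were left out. Members of a list may be named whatever their test. Some genes that the rule selects are not reported here.

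Alternatives chosen in advance were DESeq2 size factors in edgeR, no filter on low counts, a minimum mean of 1 CPM, age as a covariate, no sex covariate, the libraries of 1 time or 1 genotype alone, mice of 13.9 weeks or younger mice alone, males or females alone, a minimum absolute log2 fold change of 1, each of the 36 libraries left out in turn, and DESeq2 1.42.0 as another tool. Where 1 library is left out, its group holds 2 mice that share the spread estimated over all groups. Alternatives added after the data were seen were the removal of each library's trend on transcript GC content or on transcript length (an offset from a lowess fit with a span of 0.3, on log2 CPM with a prior count of 2), all results without the libraries of ZT16 and ZT20, and the GC correction with wild-type ZT16 replicate 3 left out. GC content and length are those of the longest GENCODE M21 transcript of the gene ID; 20430 of the 21654 IDs matched the gene name table, and 12906 of the genes tested (97.8%) had a GC value.

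Group labels were reassigned in 50 splits of the libraries for each result, or in all 10 splits of the 6 libraries at 1 time, the real split included. The models were also tested on simulated data for 13201 genes, with 200 changed genes per comparison at 1.5-fold and 2-fold; a gene changed for another comparison that a contrast also sees was not counted as unchanged. Of the genes with a 2-fold change, 92% were recovered over all times, 46% at ZT8, 6% for the interaction, 54% for the wild-type rhythm, 22% for a differing rhythm, 82% for sex in wild type and 57% for a sex difference that differs. At 1.5-fold, these were 76%, 10%, 0%, 15%, 0%, 56% and 20%. Calls among unchanged genes numbered 19 of 258 over all times, 6 of 126 at ZT8 and 7 or fewer in each of the other comparisons. The simulated counts were independent between genes, with no contrast of ZT16 and ZT20, no GC trend and no library that mismatched its sex label. They therefore do not show how many real calls such structure may bring. Body weight and age were compared with exact two-sided permutation tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.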

Results

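The series holds counts of liver mRNA from 36 mice, 3 for each of 12 groups formed by 2 genotypes and 6 times of day. It asks, by its title, what the prenatal loss of Bmal1 does to liver gene expression over a day. BMAL1 is the transcription factor that, with CLOCK or NPAS2, drives the molecular clock through E-box sequences. Each genotype had 9 mice labelled male and 9 labelled female, aged 6.4 to 13.9 weeks. Total counts ranged from 12657858 to 12839653 per library, and 13201 of 21654 genes had enough reads to be tested. A value below is a mean over 3 mice for a group and over 18 mice for a genotype, unless another n is given.

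The libraries of ZT16 and ZT20 lay apart from all others, and 1 library did not match its sex label. The 12 libraries of ZT16 and ZT20 lay between 14.2 and 102.5 on the first principal component, which held 32.8% of the variance, and the other 24 lay between -37.2 and -12.5. Over genes, which are not independent replicates, the correlation of transcript GC content with the library's deviation from the gene's mean was Spearman's rho of -0.60 to -0.15 in the 12 libraries and 0.17 to 0.47 in the 24. Wild-type ZT16 replicate 3, labelled female, had 4 reads of Xist, the transcript of the inactive X chromosome, and 1874 reads of the Y-linked gene Ddx3y. The other 8 wild-type libraries labelled female had 8604 to 15138 reads of Xist and at most 1 of Ddx3y. Its label was kept in all fits, and counts without it are given where they differ by more than 1.5 times.

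**Figure D1:**
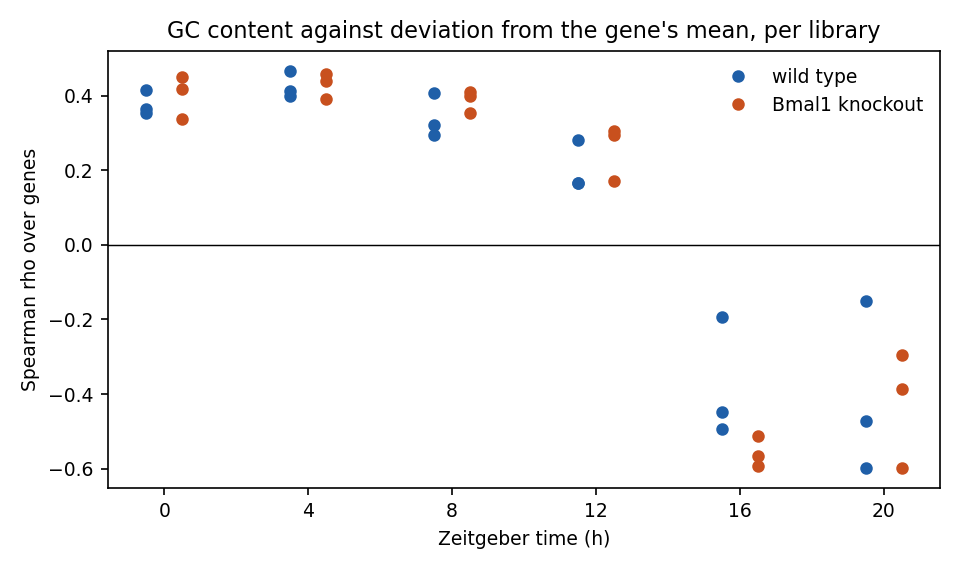
Spearman's rho over genes (y axis, no unit) between transcript GC content and a library's log2 deviation from each gene's mean, against Zeitgeber time in h (x axis), with 1 point per library and 3 libraries per genotype and time. The libraries of ZT0 to ZT12 lie between 0.17 and 0.47, and those of ZT16 and ZT20 between -0.60 and -0.15.

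Arntl (ENSMUSG00000055116, mm9 chromosome 7, 120350979 to 120457636) showed a strong day-night course in wild type and none that passed the test in knockout. In wild type it fell from 33.8 ± 0.998 CPM at ZT0 to 0.997 ± 0.234 CPM at ZT8 and stood at 38.9 ± 2.89 CPM at ZT20 (SD, n = 3). Its fitted peak was at ZT20.9, with a peak-to-trough ratio of 27.6-fold (adjusted p = 6.9e-11). In knockout, group means lay between 16.7 and 19.7 CPM at all 6 times (adjusted p = 0.85 for a rhythm), so reads of the locus were still counted there. Counts per gene do not show which exons these reads cover, so a higher value in knockout is one of reads at the locus and does not show functional mRNA. The rhythm differed between genotypes (adjusted p = 1.2e-07). The knockout value was higher by 4.15 ± 0.33 (log2, SE) at ZT8 and by 2.45 ± 0.28 at ZT12, and lower at ZT0, with -1.02 ± 0.25 (adjusted p = 0.027), and at ZT20, with -1.05 ± 0.25 (adjusted p = 0.017). The ZT0 call ended when any of the 6 libraries of that time was left out (adjusted p = 0.071 to 0.17), and the ZT20 call without wild-type replicate 1 or 3 or knockout replicate 1 or 3 (adjusted p = 0.051 to 0.090).

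In knockout, Nr1d1 and Dbp, which CLOCK:BMAL1 drives, stayed far under their wild-type daytime peaks, while Npas2 and Cry1, which REV-ERB represses, stayed high at all 6 times. Nr1d1, which encodes the repressor REV-ERBα, reached 149 ± 15.8 CPM at ZT4 in wild type and 2.67 ± 0.256 CPM in knockout. Dbp, a clock output transcription factor, reached 249.9 ± 74.9 CPM at ZT8 in wild type and 4.68 ± 1.09 CPM in knockout. Npas2, the paralog of Clock, fell in wild type to 0.0253 ± 0.0439 CPM at ZT12, where the knockout had 44.8 ± 4.21 CPM. Cry1, a repressor within the clock, was between 7.59 and 48.8 CPM in wild type and between 69.9 and 91.9 CPM in knockout. Over all times, 6 of the 20 core clock genes were higher and 9 lower, both over all genes tested and adjusted over the list alone, and 5 did not pass the test. Among those higher were Npas2 with a log2 fold change of 5.56 ± 0.17 (SE), Cry1 with 1.91 ± 0.08, Nfil3 with 0.58 ± 0.13, Clock with 0.45 ± 0.12 and Cry2 with 0.43 ± 0.13. Those lower were Bhlhe41 with -6.40 ± 0.40, Gm129 (Ciart) with -3.63 ± 0.42, Nr1d1 with -3.05 ± 0.32, Nr1d2 with -2.58 ± 0.13, Dbp with -1.74 ± 0.13, Per3 with -1.61 ± 0.13, Usp2 with -0.73 ± 0.16, Wee1 with -0.73 ± 0.20 and Tef with -0.23 ± 0.07. Rora, Hlf, Bhlhe40, Per1 and Per2 had values of 0.13, -0.01, -0.23, 0.53 and -0.18. A mean over 6 times hides differences of opposite sign: Per2 in wild type went from 14.7 ± 2.94 CPM at ZT0 to 101 ± 30.5 CPM at ZT12, and in knockout from 53.3 ± 14.1 to 32.2 ± 6.16 CPM.

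**Figure D2:**
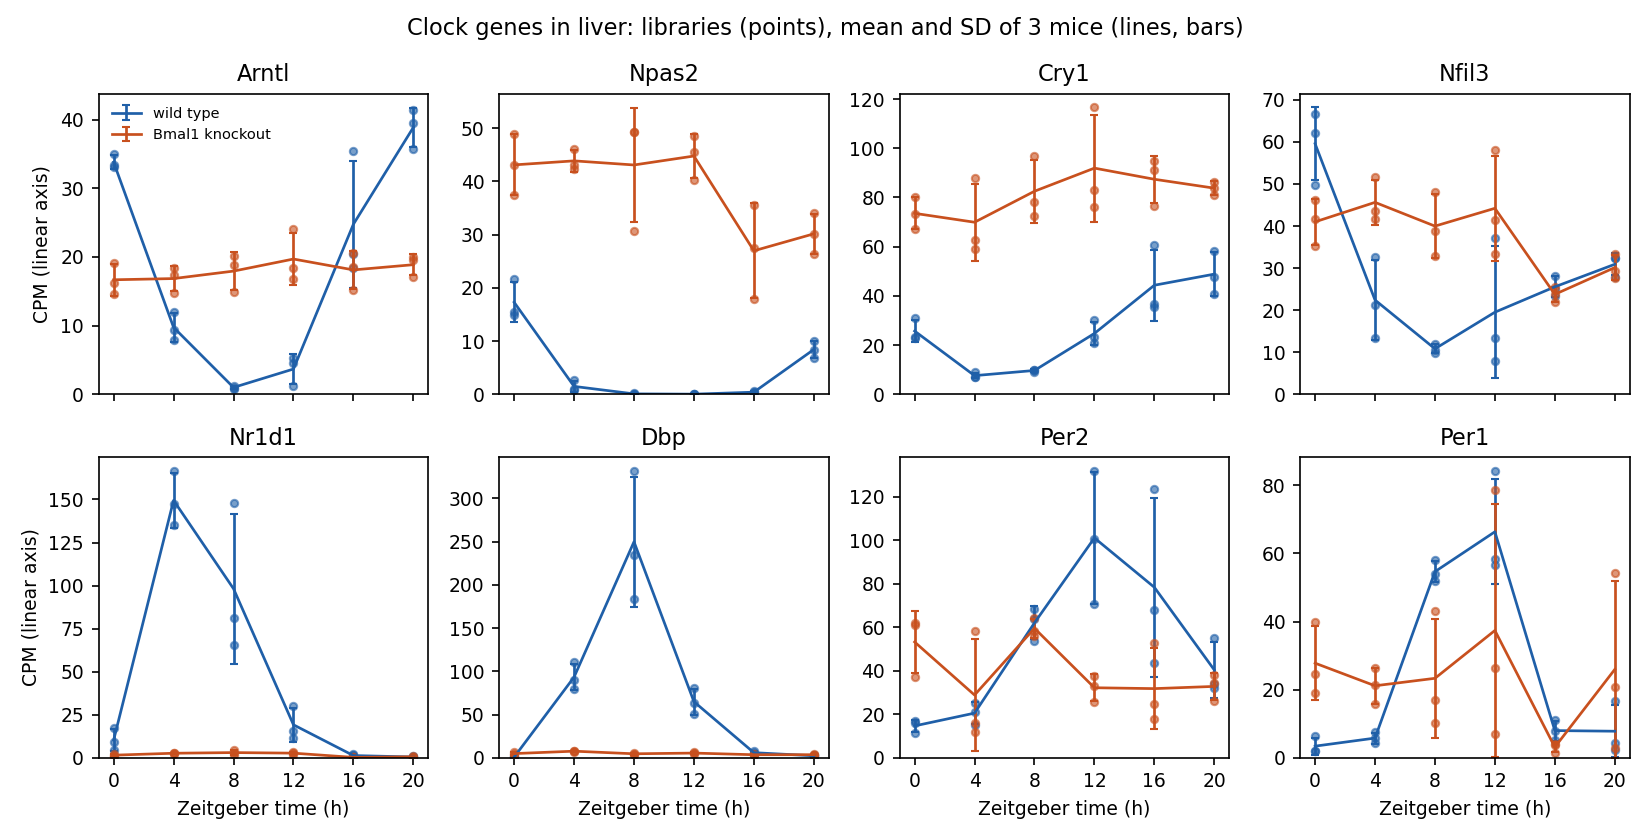
TMM-scaled CPM (y axes, linear) of 8 clock genes against Zeitgeber time in h (x axis), with 1 point per library and the mean and SD of 3 mice as line and bars, in blue for wild type and red for knockout. Nr1d1 and Dbp peak at 149 and 249.9 CPM in wild type and stay at or under 7.70 CPM on average in knockout, and Npas2 and Cry1 are higher in knockout at all 6 times.

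All 20 core clock genes were rhythmic in wild type and 6 in knockout, and the rhythm of 15 differed between genotypes. The peak-to-trough ratio in wild type was 646-fold for Npas2, 264-fold for Nr1d1, 197-fold for Dbp, 133-fold for Gm129, 34-fold for Usp2, 20.8-fold for Per1 and 17.4-fold for Per3. The fitted peaks ran from Nr1d1 at ZT6.31 and Dbp at ZT8.23, through Per3 at ZT10.6 and Per2 at ZT13.0, to Cry1 at ZT18.0, Arntl at ZT20.9 and Npas2 at ZT22.8. The 6 called in knockout were Clock, Npas2, Cry2, Nr1d1, Rora and Bhlhe40, at 2.66-fold, 1.62-fold, 2.45-fold, 6.52-fold, 2.27-fold and 3.22-fold. With each library's GC trend removed, 4 core clock genes were called in knockout, and without the libraries of ZT16 and ZT20, 0 were, against 20 and 19 in wild type. The 4 were Nr1d1, Rora, Bhlhe40 and Cry1, of which Cry1 was not among the 6. Clock, Npas2 and Cry2 lost their calls with the GC trend removed (adjusted p = 0.085, 0.48 and 0.11). The Npas2 call in knockout (adjusted p = 0.046) ended without any 1 of 13 libraries (adjusted p = 0.051 to 0.14), namely wild-type ZT0 replicates 2 and 3, ZT8 replicate 1, and knockout ZT0 replicate 2, ZT4 replicate 2, ZT8 replicates 2 and 3, ZT12 replicate 2, ZT16 replicates 1 and 3, ZT20 replicates 1, 2 and 3. The call of a differing rhythm for Clock (adjusted p = 0.037) ended without any 1 of 14 libraries (adjusted p = 0.051 to 0.085), namely wild-type ZT0 replicate 2, ZT8 replicates 1, 2 and 3, ZT12 replicates 1 and 3, ZT20 replicate 3, and knockout ZT0 replicates 1 and 2, ZT8 replicates 1, 2 and 3, ZT20 replicates 1 and 3. That for Per1 (adjusted p = 0.032) ended without any 1 of 8 (adjusted p = 0.051 to 0.066), namely wild-type ZT0 replicates 2 and 3, ZT12 replicates 1 and 3, and knockout ZT0 replicates 1, 2 and 3, ZT12 replicate 2.

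Outside the clock, the loss of Bmal1 went with large changes of single genes. Sult1e1, the estrogen sulfotransferase (mm9 chromosome 5, 88004993 to 88020636), had 0.614 ± 1.07 CPM in wild type and 61.4 ± 66.2 CPM in knockout (SD, n = 18), a log2 fold change of 7.51 ± 0.51 (SE, adjusted p = 3.7e-12). Lpl, lipoprotein lipase (chromosome 8, 71404390 to 71431347), had 33.1 ± 31 CPM in wild type and 751 ± 189 CPM in knockout, a change of 4.78 ± 0.22 (adjusted p = 5.1e-16). Cdkn1a, the cell cycle inhibitor p21 (chromosome 17, 29227924 to 29237667), had 4.99 ± 6.98 CPM in wild type and 40.7 ± 24.8 CPM in knockout, a change of 3.75 ± 0.30 (adjusted p = 8.3e-11). Cyp2a4, a steroid-hydroxylating cytochrome P450 (chromosome 7, 27092209 to 27100107), had 397 ± 496 CPM in wild type and 3.07 ± 4.2 CPM in knockout, a change of -7.86 ± 1.05 (adjusted p = 9.4e-07). Cyp2a4 stands in the female-biased list, so these means pool unlike sexes. Without wild-type ZT16 replicate 3, its wild-type mean log2 CPM was 0.90 in libraries labelled male and 9.51 in those labelled female. Its change over all times includes the ZT16 value, a fitted one that uses the sex labels. Mme, the peptidase neprilysin (chromosome 3, 63099794 to 63186153), had 45.2 ± 23.1 CPM in wild type and 1.79 ± 0.923 CPM in knockout, a change of -4.58 ± 0.20 (adjusted p = 2.7e-16). Only called genes with a mean log2 CPM of at least 1 and 1 direction at all 6 times were ranked. Beside Sult1e1, Npas2, Lpl and Cdkn1a, the 10 highest changes were those of Tox2 with 6.29 ± 0.27, Ntrk2, the BDNF receptor, with 5.36 ± 0.27, Loxl4 with 4.47 ± 0.20, Npnt with 4.26 ± 0.17, Slc34a2, a sodium-phosphate transporter, with 4.14 ± 0.31 and Grk5 with 3.61 ± 0.19. Beside Cyp2a4 and Mme, the 10 lowest included those of Nat8 with -5.30 ± 0.47, Mup15 with -4.75 ± 0.79, Col27a1 with -4.30 ± 0.35, Serpina1e with -4.06 ± 0.43, Cyp17a1 with -4.03 ± 0.53, Slc22a26 with -3.92 ± 0.60 and Clec2h with -3.64 ± 0.37. In all, 4711 of 13201 genes were called (adjusted p under 0.05), 2327 higher and 2384 lower in knockout, with 256 and 430 of them at least 2-fold. The count was 2215 among males alone and 2209 among females alone, 2686 among the mice of 13.9 weeks and 1470 among younger mice, each with fewer libraries. Sexes are those of the labels here, so the females include wild-type ZT16 replicate 3.

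REV-ERB-repressed genes were higher in knockout and E-box targets lower. Of the 9 tested REV-ERB-repressed genes, 7 were higher, Npas2 and Cry1 among them, and 1 was lower: Gys2, liver glycogen synthase, with -1.18 ± 0.08 (camera adjusted p = 4.2e-11, and 4.6e-06 with an estimated correlation). Of the 16 E-box targets, 2 were higher and 10 lower, with Nr1d2, Bhlhe41, Dbp and Per3 the 4 of smallest p (camera adjusted p = 5.0e-09; adjusted p = 0.077 with an estimated correlation). The core clock list as a whole had a camera adjusted p of 0.75, and 0.90 with an estimated correlation. Adjusted over the list alone, the counts of these 3 lists were the same.

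Genes of lipid synthesis were lower in knockout. Of 22 tested genes of cholesterol synthesis and SREBP2 targets, 21 were lower and 0 higher, the same adjusted over the list alone. Among males alone 5 were lower (median log2 fold change -0.58), among females alone 18 (-1.07), among mice of 13.9 weeks 5 (-0.59) and among younger mice 22 (-1.25), and whether sexes or ages differ in this was not tested. The females, taken by label, include wild-type ZT16 replicate 3. Insig1 had 591 ± 179 CPM in wild type and 253 ± 90.6 CPM in knockout, a log2 fold change of -1.22 ± 0.19 (SE, n = 18), Stard4 -0.91 ± 0.18 and Pmvk -0.85 ± 0.16. The list had a camera adjusted p of 6.4e-08, and an adjusted p = 0.57 with an estimated correlation. Of 20 genes of fatty acid and triglyceride synthesis, 16 were lower and 1 higher (17 and 1 adjusted over the list alone), with Acacb at -2.10 ± 0.28, the elongase Elovl6 at -1.57 ± 0.22, malic enzyme Me1 at -0.88 ± 0.13 and Gpam at -0.87 ± 0.13 (camera adjusted p = 5.0e-07; adjusted p = 0.33 with an estimated correlation). Of 21 genes of fatty acid oxidation and PPARα targets, 2 were higher and 7 lower, and 1 was higher without any 1 of 17 libraries, namely wild-type ZT0 replicate 2, ZT4 replicates 1 and 2, ZT8 replicates 2 and 3, ZT12 replicates 2 and 3, ZT16 replicate 1, and knockout ZT0 replicates 1 and 3, ZT4 replicate 2, ZT8 replicates 2 and 3, ZT12 replicates 1 and 2, ZT16 replicate 2, ZT20 replicate 3. Acaa1b stood at -1.01 ± 0.13 and Ppara itself at -0.92 ± 0.16, while Pdk4, which restrains glucose oxidation, was higher with 1.81 ± 0.20 (camera adjusted p = 0.19; 0.90 with an estimated correlation).

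Markers of macrophages were lower in knockout, all 13 of the Kupffer cell list. Timd4 had 5.03 ± 2.18 CPM in wild type and 2.45 ± 1.38 CPM in knockout, a log2 fold change of -1.07 ± 0.17 (SE, n = 18), the complement gene C1qa -0.83 ± 0.15, Lyz2 -0.79 ± 0.15 and C1qc -0.70 ± 0.14. Camera gave an adjusted p of 8.0e-06, and an adjusted p = 0.57 with an estimated correlation. Sinusoidal endothelial markers were lower in 9 of 14 and higher in 0, with Flt1 at -0.50 ± 0.08, Fcgr2b at -0.44 ± 0.09, Kdr at -0.39 ± 0.08 and Eng at -0.35 ± 0.08 (camera adjusted p = 0.025; adjusted p = 0.90 with an estimated correlation). Of 20 acute phase and inflammation genes, 2 were higher and 9 lower, with Saa4 at -1.51 ± 0.13, Orm3 at -2.46 ± 0.29, Cxcl1 at -1.17 ± 0.21 and the fibrinogen chain Fgb at 0.33 ± 0.07 (camera adjusted p = 0.025; adjusted p = 0.57 with an estimated correlation). Counts adjusted over the list alone were the same for these 3 lists. Without the libraries of ZT16 and ZT20, the acute phase list had an adjusted p of 0.092 and the endothelial list of 0.24. The endothelial call also ended without knockout ZT4 replicate 2 (adjusted p = 0.0503), and 1 endothelial marker was called higher without any 1 of wild-type ZT16 replicate 2, ZT20 replicate 2, and knockout ZT20 replicate 2.

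Among the metabolic lists that camera did not call, single genes still moved strongly. Of 24 genes of drug and xenobiotic metabolism, 11 were higher and 9 lower, with the cytochromes Cyp2c55 at 3.29 ± 0.31, Cyp2c29 at 1.43 ± 0.11 and Cyp2c37 at 0.99 ± 0.10, and Cyp2a5 at -1.91 ± 0.14. Of 19 NRF2 targets, 5 were higher and 9 lower, with the glutathione transferase Gstm3 at 2.64 ± 0.22 and Gsta2, Mgst3 and Gsta4 at -1.63 ± 0.25, -1.15 ± 0.18 and -1.12 ± 0.15. Of 19 genes of glucose and glycogen metabolism, 5 were higher and 7 lower (6 and 9 adjusted over the list alone), with the glucose transporter Slc2a2 at -0.98 ± 0.11, the branching enzyme Gbe1 at -0.43 ± 0.06 and Ppp1r3c at 1.23 ± 0.15. Of 15 genes of bile acid synthesis and transport, 4 were higher and 3 lower, with Slco1a4 at 1.03 ± 0.19, Hsd3b7 at 0.61 ± 0.06, Akr1d1 at -0.54 ± 0.11 and the bile acid receptor gene Nr1h4 at -0.27 ± 0.08. Adjusted over the list alone, the counts for drug metabolism, NRF2 targets, fatty acid oxidation and bile acids were the same. Camera adjusted p values were 0.82 for drug metabolism, 0.45 for NRF2 targets, 0.14 for glucose and glycogen and 0.75 for bile acids, and 0.90, 0.90, 0.64 and 0.90 for these lists with an estimated correlation. The bile acid list had a median log2 fold change of -0.02 and a mean of 0.06.

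**Figure D3:**
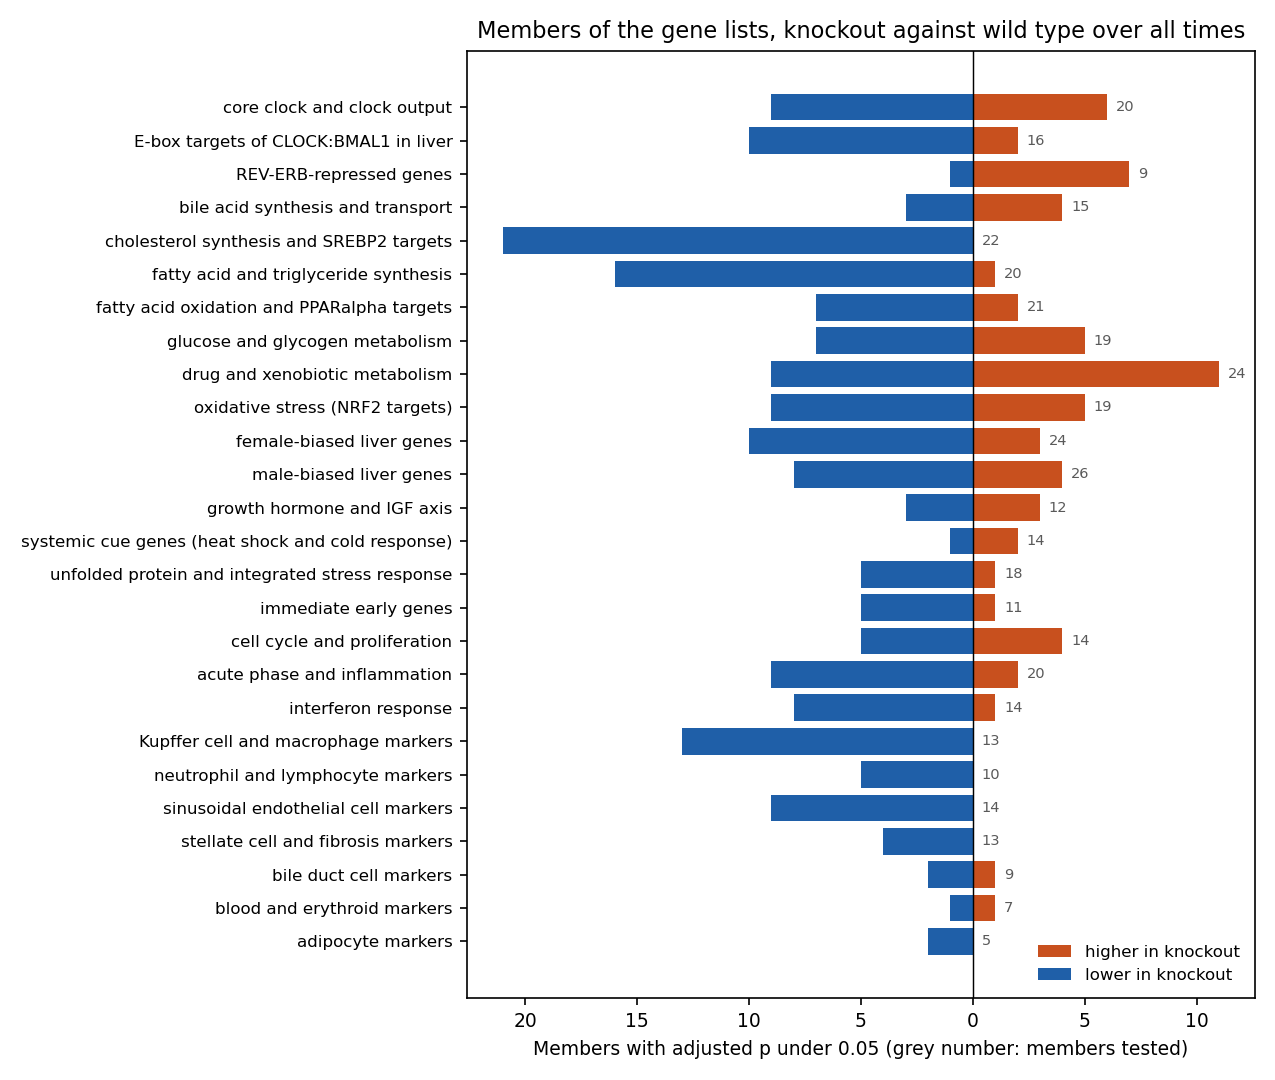
Number of members called higher (red, right) and lower (blue, left) in knockout over all times at an adjusted p under 0.05 (x axis, genes), for the 26 lists with at least 5 tested genes (y axis), with the number tested in grey. The cholesterol list has 21 of 22 lower, the Kupffer cell list 13 of 13 lower and the REV-ERB-repressed list 7 of 9 higher.

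At each of the 6 times, between 260 and 1574 genes differed between genotypes. There were 260 at ZT0, 470 at ZT4, 1130 at ZT8, 1574 at ZT12, 1136 at ZT16 and 446 at ZT20. Among called genes with a mean log2 CPM of at least 1, the highest at ZT0 were Sult1e1 with a log2 fold change of 7.0 ± 1.21 (SE, n = 3), Tox2 with 6.73 ± 0.62 and Ntrk2 with 6.50 ± 0.71. The lowest were Lars2 with -5.33 ± 0.97, Nat8 with -5.15 ± 1.11 and Serpine2 with -4.47 ± 0.63. Lars2, a mitochondrial leucyl-tRNA synthetase, rested on wild-type ZT0 replicate 2, without which its adjusted p was 0.97. Nat8 lost its call without knockout replicate 1 or 2 or wild-type replicate 3 (adjusted p = 0.059 to 0.11). At ZT4 the highest were Sult1e1 with 9.28 ± 1.52, Tox2 with 6.42 ± 0.61 and Ntrk2 with 5.93 ± 0.67, and Nr1d1 with -5.80 ± 0.58 and Mme with -3.84 ± 0.47 were among the 3 lowest. At ZT8 the highest were Sult1e1 with 9.75 ± 1.52, Npas2 with 8.92 ± 0.50 and Slc34a2 with 8.06 ± 1.02, and the lowest Slc22a26 with -7.10 ± 2.06, Nat8 with -5.84 ± 1.12 and Dbp with -5.73 ± 0.33. Slc22a26 lost its call without wild-type ZT8 replicate 1 (adjusted p = 0.26) or knockout ZT8 replicate 3 (adjusted p = 0.74). Each of these was the only female of its group. Fitted without wild-type ZT16 replicate 3, Slc22a26 was higher in females than in males, by 9.29 (log2) in wild type and 8.33 in knockout. Sex and single mice thus cannot be told apart in these lost calls.

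At ZT12 the highest were Npas2 with 10.31 ± 0.56 (SE, n = 3), Sult1e1 with 7.71 ± 1.20 and Tox2 with 7.11 ± 0.66, and the lowest Mup15 with -8.12 ± 2.31, Cyp2a4 with -7.17 ± 2.18 and Nat8 with -6.45 ± 1.47. These 3 low calls ended when single ZT12 libraries were left out: Mup15 without any of the 3 knockout ones (adjusted p = 0.064 to 0.10), Cyp2a4 without knockout replicate 1 or 2 or wild-type replicate 2 or 3 (adjusted p = 0.058 to 0.17), and Nat8 without wild-type replicate 1 or knockout replicate 3 (adjusted p = 0.067 to 0.11). The libraries named for Cyp2a4 were the females of ZT12, and those for Nat8 the only male of each genotype there. Whether sex accounts for these losses was not tested. At ZT16 the highest were Xist with 8.82 ± 2.15, Hao2, a hydroxyacid oxidase gene of the female-biased list, with 7.52 ± 1.11 and Npas2 with 6.10 ± 0.41, and the lowest Cyp2a4 with -15.27 ± 3.11, Serpina1e with -7.98 ± 1.25 and Nat8 with -7.31 ± 1.09. The Cyp2a4 value is a fitted one, which uses the sex labels, and no measured fold: the group means were 193 ± 332 CPM in wild type and 0.361 ± 0.403 CPM in knockout. Without wild-type ZT16 replicate 3, the library labelled female with 4 reads of Xist, Xist stood at -0.07 (adjusted p = 0.98) and Hao2 lost its call (adjusted p = 0.13). Xist also lost it without knockout replicate 3 (adjusted p = 0.092), and Cyp2a4 without wild-type replicate 1 (adjusted p = 0.59). At ZT20 the highest were Tox2 with 6.70 ± 0.84, Sult1e1 with 5.36 ± 1.08 and Lpl with 4.38 ± 0.51, and the lowest Mme with -4.98 ± 0.48, Sult3a1 with -4.92 ± 0.71 and Col27a1 with -4.28 ± 0.85. Sult1e1 lost its ZT20 call without knockout replicate 3 (adjusted p = 0.067).

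Where a group of 3 libraries held 1 to 3 reads of a gene in all, the fitted value is loose, and the ratio of the scaled reads is given with its exact 95% interval for counting error only. At ZT12 Npas2 was higher by 1739-fold (312 to 68719), at least 384-fold without wild-type replicate 2 (with the 0 reads left set to 3 over the group) and 1127-fold (202 to 44543) without wild-type replicate 3. Nat8 was lower at ZT12 by 159-fold (54 to 773), 11.6-fold (3.51 to 59.9) without wild-type replicate 1, 238-fold (81.0 to 1159.9) without wild-type replicate 3, 106-fold (35.9 to 514) without knockout replicate 1 and at least 104-fold without knockout replicate 2. At ZT8 Npas2 was higher by 549.8-fold (188 to 2669), 366-fold (125 to 1778) without wild-type replicate 2 and 1096-fold (197 to 43331) without wild-type replicate 3. Sult1e1 was higher at ZT8 by 962-fold (266 to 7949), 639-fold (177 to 5284) without wild-type replicate 3 and 444-fold (122 to 3673) without knockout replicate 3. At ZT4 it was higher by 766-fold (212 to 6335), 506-fold (139.8 to 4182) without wild-type replicate 1 and 417-fold (115 to 3450.2) without knockout replicate 2. Tox2 was higher at ZT20 by 119-fold (32.7 to 991).

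The counts per time moved by more than 1.5 times with single libraries. At ZT0 they were 169, 96 and 94 without wild-type replicates 1, 2 and 3, and 137, 106 and 157 without knockout replicates 1, 2 and 3. At ZT4 they were 244, 265 and 236 without wild-type replicates 1, 2 and 3, and 287 and 222 without knockout replicates 1 and 3. At ZT8, 753 and 656 genes were called without knockout replicates 1 and 3. At ZT12, 1046, 932 and 1019 were called without wild-type replicates 2 and 3 and knockout replicate 2. At ZT16, 2542 were called without wild-type replicate 1, the library farthest out on the first principal component (102.5), more than the 1867 of ZT12 without it, and 652, 756 and 663 without knockout replicate 1, wild-type replicate 2 and knockout replicate 3. At ZT20, 279, 245 and 200 were called without wild-type replicate 1 and knockout replicates 1 and 3. With only the libraries of that time, 75 genes were called at ZT16 and 6 at ZT20, and 943 and 1156 at ZT0 and ZT4. Without the libraries of ZT16 and ZT20, the counts of ZT0, ZT4, ZT8 and ZT12 were 797, 1353, 2158 and 2887.

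**Figure D4:**
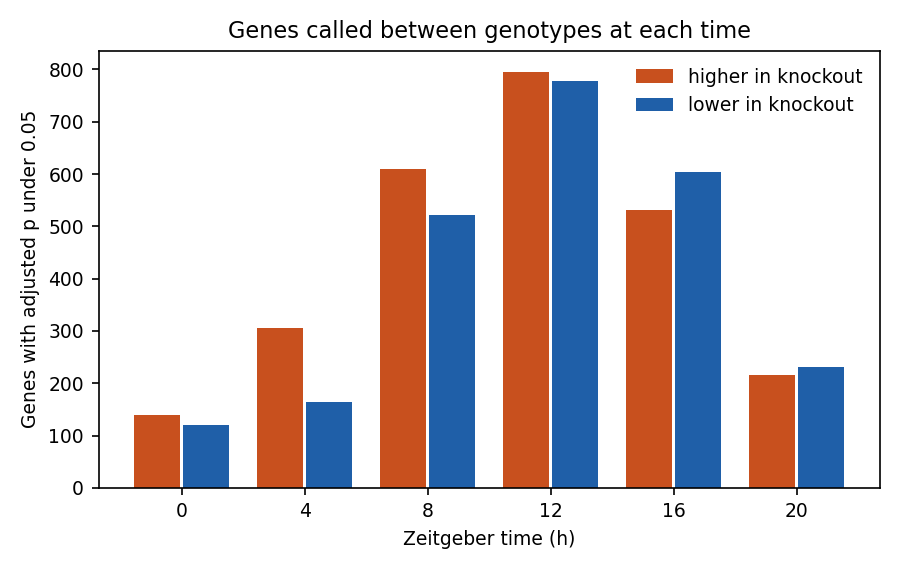
Number of genes called higher (red) and lower (blue) in knockout at an adjusted p under 0.05 (y axis, genes) against Zeitgeber time in h (x axis), from 3 mice per genotype and time and 13201 genes tested. The bars are tallest at ZT12, with 796 higher and 778 lower, and shortest at ZT0, with 140 and 120.

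The knockout effect differed between times for 221 genes, 14 of the 20 core clock genes among them. Chka, choline kinase α, fell from 169 ± 5.96 CPM at ZT0 to 16.9 ± 1.82 CPM at ZT8 in wild type, and had 178 ± 55.2 and 227 ± 3.04 CPM in knockout (SD, n = 3). Insig2, which restrains SREBP activation, went from 408 ± 53.3 to 77.5 ± 9.08 CPM in wild type and had 499.8 ± 75.5 and 534 ± 82.5 CPM in knockout. The mitochondrial unfoldase gene Clpx went from 393 ± 11 to 71.6 ± 8.09 CPM and had 489 ± 43.6 and 536 ± 7.39 CPM. The log2 fold changes at ZT8 were 3.75 ± 0.24 for Chka, 2.79 ± 0.25 for Insig2 and 2.91 ± 0.24 for Clpx, and those at ZT20 were 0.17 ± 0.21, 0.64 ± 0.23 and 0.42 ± 0.22. Outside the clock list, the 10 smallest adjusted p ran from 1.5e-09 for Arntl and 4.0e-09 for Chka, through Slc30a10, Dtx4, Cldn1, Clpx, Ppp1r3b, Asap2 and Insig2, to 2.1e-05 for Tubb2a. Without wild-type ZT16 replicate 1 the count was 372, without the libraries of ZT16 and ZT20 it was 454, and DESeq2 gave 493.

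Across all genes, 7451 were called rhythmic in wild type and 6382 in knockout, and the rhythm of 294 differed between genotypes. The 10 smallest p for a differing rhythm included those of Npas2, Chka, Clpx, Cry1, Arntl, Dbp, Slc30a10, Insig2 and Loxl4, with adjusted p from 2.4e-15 for Npas2 to 1.1e-06 for Loxl4. Chka peaked at ZT21.0 in wild type with a ratio of 12.8-fold and had 1.23-fold in knockout. The manganese exporter gene Slc30a10 had 6.72-fold against 1.18-fold, and Loxl4 27.4-fold against 1.38-fold. Among called genes with a mean log2 CPM of at least 1, the 10 largest amplitudes in wild type were those of Npas2, Nr1d1, Dbp, Usp2, the male-biased genes Mup1, Mup7 and Mup14, and the Y-linked genes Ddx3y, Eif2s3y and Uty. The fits of the last 6 peaked near ZT16, and without wild-type ZT16 replicate 3, labelled female, Mup1, Mup7, Mup14 and Ddx3y lost their calls (adjusted p = 0.94, 0.99, 0.89 and 0.075). Without the libraries of ZT16 and ZT20, all 6 did (adjusted p = 0.17 to 0.99).

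Within the same limit, the 10 largest amplitudes in knockout were those of A1bg, Lcn2, Lrp5, Zfpm1, Nfic, Nfix, Pigt, Setd1b, Eif4ebp2 and Spen. They ran from 28.9-fold for A1bg to 11.1-fold for Spen. Nfix, a transcription factor gene, had 12.3-fold with a peak at ZT6.07 in knockout and 13.8-fold with a peak at ZT6.30 in wild type. The acute phase gene Lcn2 had 18.9-fold in knockout and 1.95-fold in wild type, and the test of the difference gave an adjusted p of 0.11. With all libraries, none of the 10 was called for a differing rhythm. None was called in knockout without the libraries of ZT16 and ZT20 (adjusted p = 0.14 to 0.91). In that fit, only Lrp5 of the 10 was called for a differing rhythm (adjusted p = 0.0011). A1bg also lost its call without knockout ZT4 replicate 3 or ZT16 replicate 3 (adjusted p = 0.071 and 0.058), and Lcn2 without knockout ZT4 replicate 2 (adjusted p = 0.17). With each library's GC trend removed, 5855 genes were rhythmic in wild type, 3447 in knockout, and 404 differed. Without the libraries of ZT16 and ZT20, which leaves 4 times, these were 2113, 94 and 468.

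More glucose and glycogen genes were called rhythmic in wild type than in knockout, and fewer cholesterol genes. Of 19 glucose and glycogen genes, 17 were rhythmic in wild type and 4 in knockout, with 5 differing, among them Gys2 and Ppp1r3b. The E-box targets had 16 of 16 rhythmic in wild type, 2 in knockout and 10 differing. The REV-ERB-repressed genes had 8, 3 and 6 of 9, and the drug metabolism genes 18, 10 and 1 of 24. Of the 22 cholesterol genes, 5 were rhythmic in wild type, 13 in knockout and 0 differed. With the GC trend removed, glucose and glycogen genes had 14, 4 and 4, E-box targets 15, 1 and 11, REV-ERB-repressed genes 8, 2 and 6, drug metabolism genes 13, 4 and 2, and cholesterol genes 4, 10 and 1. Without the libraries of ZT16 and ZT20, these 5 lists had 0 rhythmic genes in knockout, and 14, 16, 7, 8 and 1 in wild type.

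Most liver genes known to differ between the sexes did so in both genotypes, and the female-biased genes Sult3a1 and Cyp2b13 had lower means in knockout females. Of 24 tested female-biased genes, 23 were higher in females of the wild type and 18 in knockout females. Rtp3 was called higher in males instead, with -0.54 ± 0.14 in wild type and -0.56 ± 0.15 in knockout (female to male, log2, SE). Both calls ended when single libraries were left out, the first without any 1 of wild-type ZT0 replicate 1, ZT4 replicate 3, ZT12 replicate 1, ZT20 replicates 1, 2 and 3, the second without either of knockout ZT4 replicate 2, ZT16 replicate 3 (adjusted p = 0.051 to 0.15 and 0.066 to 0.12). Of 26 male-biased genes, 18 and 22 were higher in males. Sult3a1, a sulfotransferase, had 132 ± 102 CPM in wild-type females and 11.8 ± 9.38 CPM in knockout females, against 0.0254 ± 0.0381 and 0.0396 ± 0.0659 CPM in males (SD, n = 9). Cyp2b13, a female-biased cytochrome P450, had 411 ± 215 and 24.7 ± 13.7 CPM in females and 0.144 ± 0.245 and 1.08 ± 0.497 CPM in males. Its female-to-male log2 difference was 11.16 ± 0.53 in wild type and 4.31 ± 0.37 in knockout, and the change of that difference passed the test (adjusted p = 4.6e-06), which that of Sult3a1 did not (adjusted p = 0.72). Hao2, also female-biased, was higher in knockout over all times (3.37 ± 0.30), with 9.43 ± 6.14 CPM in wild-type and 60.0 ± 25.9 CPM in knockout females. Serpina12, an adipokine gene of the male-biased list, was higher too (2.69 ± 0.37), and in males it had 29 ± 14.3 and 327 ± 139 CPM. Moxd1 had 0.272 ± 0.357 and 88.9 ± 68.9 CPM in males and at most 0.02 CPM on average in females of either genotype. Its knockout effect over all times (8.41 ± 0.63) lost its call without knockout ZT4 replicate 2 (adjusted p = 1), ZT12 replicate 3 (adjusted p = 1) or ZT20 replicate 2 (adjusted p = 0.055). Each of these was the only male of its group, and all knockout females together had 1 read of Moxd1. Leaving it out empties the group of Moxd1 reads or nearly so. The lost calls therefore do not show that the higher mean in knockout males rests on single mice.

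The labels gave 527 genes that differed between the sexes in wild type, 273 higher in females and 254 higher in males, and 853 in knockout, 449 and 404. In wild type the 5 highest in females were Sult3a1, Cyp3a41a, Cyp2b13, Xist and Sult2a2, from 11.58 ± 0.64 to 10.17 ± 0.60, and the 5 lowest Mup7, Mup14, Eif2s3y, Ddx3y and Cyp4a12b, from -7.57 ± 1.18 to -6.17 ± 0.74. These low values count wild-type ZT16 replicate 3 as female, although its reads do not match that label. Without it, Ddx3y, Eif2s3y, Kdm5d and Uty stood at -11.86, -11.46, -10.99 and -10.78. Mup7, Mup14 and Cyp4a12b then stood at -8.52, -8.34 and -7.41. In knockout the highest were Xist, A1bg, Slc22a26, Dmbt1 and Sult3a1, from 11.66 ± 0.68 to 7.77 ± 0.65, and the lowest Moxd1, Eif2s3y, Ddx3y, Kdm5d and Uty, from -12.31 ± 0.76 to -9.26 ± 1.03. In wild type, reads of Sult3a1 were 4892-fold (1674 to 23723) higher in females, with 3 reads in all males, and Cyp3a41a was at least 616-fold higher, with 0 reads in males set to 3 over the group, and at least 208-fold higher without ZT0 replicate 1. In knockout, the ratio of males to females was 10177-fold (1826 to 402030) for Moxd1, 886-fold (303 to 4298) for Kdm5d and 888-fold (303 to 4307) for Uty. Without knockout ZT16 replicate 3, which held 3 of the 3 reads of Kdm5d and 2 of the 3 of Uty in females, the ratio was at least 786-fold for Kdm5d and 2362-fold (423 to 93319) for Uty, and Moxd1 in males was at least 3009.9-fold higher without knockout ZT20 replicate 1. Dmbt1 (8.23 ± 1.84, 342-fold (94.3 to 2828)) lost its call without knockout ZT16 replicate 1 or 2 (adjusted p = 0.085 and 0.083) and stood at -1.23 without knockout ZT16 replicate 3, which held all 743 reads in females (adjusted p = 0.83). Without knockout ZT8 replicate 2 it was at least 201-fold higher. In wild type, 1191 genes were called without ZT16 replicate 3, whose reads do not match its label, 1080 without ZT16 replicate 1, and 240, 311, 287 and 239 without ZT12 replicate 1, ZT0 replicate 1, ZT20 replicate 2 and ZT4 replicate 3. In knockout, 517, 438 and 494 were called without ZT4 replicate 2, ZT20 replicate 2 and ZT0 replicate 3. In both genotypes, each library whose removal lowered the count here was the only one of its labelled sex in its group. Without it, that group held no comparison of the sexes, so the lower counts do not show that the calls rest on unusual libraries.

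A sex difference that changed with genotype was called for 13 genes. The 10 of smallest p were Cyp2b13, Cdx4, Ugt1a9, Cela1, Lrtm1, Cib3, Chic1, Crybb3, Aldh3a2 and Arsa. Cela1, an elastase gene, had 22 ± 5.26 CPM in wild-type and 94.1 ± 40.0 CPM in knockout males, and 16.0 ± 10.6 and 12.6 ± 7.17 CPM in females (SD, n = 9; adjusted p = 4.8e-04). Ugt1a9, a glucuronosyltransferase gene, had 36.1 ± 11.5 and 1.63 ± 0.580 CPM in males and 57.8 ± 27.8 and 16.8 ± 10.0 CPM in females (adjusted p = 4.8e-04). The X-linked neighbours Cdx4 and Chic1 had higher means in knockout in both sexes, Chic1 with 7.80 ± 5.61 and 49.1 ± 16.9 CPM in males and 18.2 ± 11.2 and 37.3 ± 11.3 CPM in females. Aldh3a2 lost its call without any 1 of 7 libraries (adjusted p = 0.052 to 0.13), namely wild-type ZT4 replicate 3, ZT12 replicate 1, and knockout ZT0 replicate 2, ZT4 replicate 2, ZT12 replicate 3, ZT16 replicate 3, ZT20 replicate 2. Arsa lost it without any 1 of 19 (adjusted p = 0.050 to 0.13), namely wild-type ZT0 replicates 1 and 2, ZT4 replicates 2 and 3, ZT12 replicates 1, 2 and 3, ZT20 replicates 1, 2 and 3, and knockout ZT0 replicates 2 and 3, ZT4 replicates 1 and 2, ZT12 replicate 3, ZT16 replicates 1 and 3, ZT20 replicates 2 and 3. Crybb3 lost it without wild-type ZT8 replicate 1 (adjusted p = 0.059) or knockout ZT20 replicate 2 (adjusted p = 0.063). The count was 40 without wild-type ZT16 replicate 3 and 31 without wild-type ZT16 replicate 1, 23 and 24 without knockout ZT8 replicates 2 and 3, 8 without wild-type ZT12 replicate 1, knockout ZT0 replicate 2 or knockout ZT16 replicate 3, and 7 without knockout ZT20 replicate 2. Without wild-type ZT16 replicate 3, 23 male-biased genes were called in wild type and 21 female-biased genes in knockout, and the sex difference of 4 female-biased and 3 male-biased genes changed with genotype. DESeq2 called 61 genes for the interaction and 824 for sex in wild type.

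**Figure D5:**
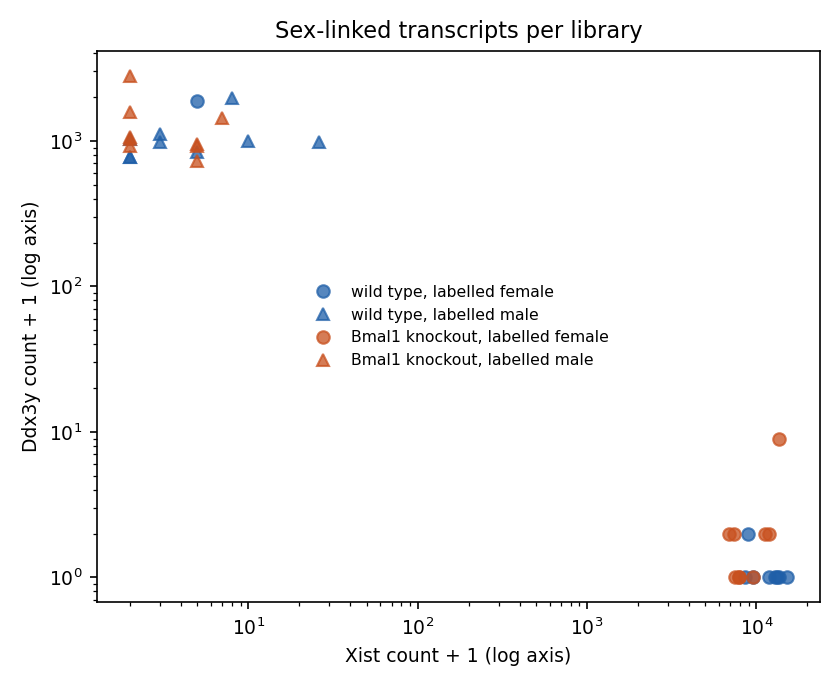
Reads of Ddx3y plus 1 (y axis, log scale) against reads of Xist plus 1 (x axis, log scale), with 1 point per library, shape by labelled sex and colour by genotype, 9 libraries for each combination. The library with 4 reads of Xist and 1874 of Ddx3y, wild-type ZT16 replicate 3, is labelled female and lies among those labelled male.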

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

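Tests chosen after the data were seen were those of a mixture and of a swap for wild-type ZT16 replicate 3, those of cages, and every value with the GC or length trend removed or without single times.

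Wild-type ZT16 replicate 3, labelled female, stood far from the 8 other wild-type libraries labelled female in 5 sex-linked genes. It had 4 reads of Xist, the transcript of the inactive X chromosome, where the others had 8604 to 15138. It had 1874 reads of Ddx3y and 1742 of Eif2s3y, where the others had 0 to 1 and 0 to 2, and 399 of Kdm5d and 426 of Uty, where the others had 0. A wrong sex label is a candidate explanation: all 24 tested genes of the female-biased list lay nearer to the mean of the libraries labelled male. A mixture of male and female RNA would bring Xist reads, and its 4 reads were no more than the 25 of a library labelled male. A swap within the series would leave a library labelled male with female counts, and the highest Xist count among those was 25. An error in the label and an animal from outside the series stay open, and no biological explanation was tested.

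The count of rhythmic genes in knockout, 6382, goes with a contrast between the 12 libraries of ZT16 and ZT20 and the other 24. With each library's trend on transcript GC content removed, 3447 genes were called, so a GC-content bias between libraries may account for part of the count. With the trend on transcript length removed, 6487 were called, which argues against a length bias. The part that stays after the GC correction may be technical or biological, since the labels do not say which libraries were prepared or sequenced together and the contrast follows the times themselves. Cage does not coincide with the contrast, since 5 cages held mice of both sets of times. Without the 12 libraries, 94 genes were called in knockout and 2113 in wild type, with fewer times and libraries in the fit.

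All 13 Kupffer cell and macrophage markers were lower in knockout, among them Timd4, C1qa, Lyz2 and C1qc. With the GC trend removed, 13 were lower, and with age as a covariate, 13 were lower, which argues against both as the cause. A lower share of all cells other than hepatocytes would lower other markers alike, if these cells fall in proportion and alone express the markers. Neither condition was tested. The mean log2 change was -0.76 (SE 0.15) over the 13 Kupffer markers and -0.22 (SE 0.07) over the 14 endothelial ones, and their difference was 4.64 times its standard error. Under those conditions only, this argues against such a share by itself. Such a share together with a further fall of Kupffer markers stays open, since the endothelial mean was lower too. A lower share of leukocytes in general stays open, since the 10 neutrophil and lymphocyte markers had a mean of -0.64, with 5 lower. Fewer Kupffer cells and lower expression within them stay open too, as hypotheses that a count of these cells in tissue would test.

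Knockout ZT16 replicate 3, labelled female, had 8 reads of Ddx3y where the other 8 knockout libraries labelled female had 0 to 1, 2 of Eif2s3y and 2 of Uty where they had 0 to 1, and 3 of Kdm5d where they had 0. Its total count was 12827619, where theirs were 12695895 to 12760144. Wild-type ZT16 replicate 1, labelled male, had 1957 reads of Ddx3y where the other 8 had 777 to 1118, 1998 of Eif2s3y where they had 773 to 1252, and 531 of Uty where they had 206 to 235. Knockout ZT16 replicate 1, labelled male, had 2797 reads of Ddx3y where the others had 722 to 1586. Wild-type ZT8 replicate 3, labelled male, had 25 reads of Xist where the others had 1 to 9. The mouse of knockout ZT12 replicate 3, a male, weighed 18.4 g where the other 8 knockout males weighed 22.5 to 26.5 g. In all, 28 groups of 9 were tested for a value far from the rest, and 16 values stood out. For normally distributed values chance flags about 1 in 20 groups; counts near 0 do not follow that, and linked genes flag the same library again, so 16 cannot be set against it.

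The knockout effect differed between times for 221 genes, Arntl, Chka and Insig2 among them. The 24 h rhythm differed between genotypes for 294, Npas2, Cry1 and Dbp among them, and the sex difference for 13, with Cyp2b13 of smallest p. In 50 splits of the libraries, the highest count of the others was 142 for the first, 13 for the second and 2 for the third. For each, only the real split gave as many genes. The same holds for the genotype effect over all times (4711, highest other 62), the rhythm in wild type (7451, highest other 42) and in knockout (6382, highest other 26), and sex in wild type (527, highest other 58) and in knockout (853, highest other 1). Random labels would thus rarely give such counts. The splits cannot exclude a structure of the samples that follows the same division. For the rhythm in each genotype, times were shuffled over its mice, which breaks up the libraries of ZT16 and ZT20. Reassigned labels also leave the real effects in the spread, which may lower the other counts. For the gene lists, 22 of 50 splits gave at least the 7 called lists, with a highest other of 12, so chance cannot be excluded for that number.

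At 1 time, 3 libraries against 3 make 10 splits, too few for a share under 0.05. The real count and the highest of the 9 other splits were 260 and 3 at ZT0, 470 and 0 at ZT4, 1130 and 1 at ZT8 and 1574 and 3 at ZT12. At ZT16 they were 1136 and 2507, and at ZT20 446 and 2634, each with 2 of 10 splits at least as large as the real one. The ZT16 split of 2507 set wild-type replicate 1 and knockout replicates 1 and 3, at 102.5, 92.2 and 66.8 on the first principal component, against the 3 others, at 16.9 to 60.6. The ZT20 split of 2634 set wild-type replicates 1 and 3 and knockout replicate 2, at 41.0, 82.8 and 78.0, against the 3 others, at 14.2 to 19.7. Both point to a structure of the samples along that component, and the labels do not say which libraries were prepared or sequenced together. Cages do not follow these splits: the 1 cage with 2 or more mice at ZT16 and the 2 such cages at ZT20 had mice on both sides. With the GC trend removed, the real counts were 1146 and 513.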

How the results depend on the processing

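Alternatives chosen after the data were seen were the removal of the GC or length trend, alone or with wild-type ZT16 replicate 3 left out, and the fits without ZT16 and ZT20. The counts over all times, for both rhythms and for sex in knockout stayed within 1.5 times under DESeq2 size factors, no filter, a minimum of 1 CPM, age as a covariate and DESeq2. The cause of a change named below was not tested, except that a stricter threshold lowers a count by construction. Fewer libraries went with lower counts in some results and with higher counts in others.

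Over all times (4711), 2686 genes were called among mice of 13.9 weeks, 1470 among younger mice, 2215 among males, 2209 among females and 686 with an absolute log2 fold change of at least 1. Males and females are those of the labels, with wild-type ZT16 replicate 3 among the females. That minimum gave 310 at ZT4, 681 at ZT8, 907 at ZT12, 622 at ZT16 and 277 at ZT20, and the share of higher genes went to 37.3% over all times, 35.5% at ZT16 and 35.7% at ZT20. No sex covariate gave 152 at ZT0, 309 at ZT4 and 293 at ZT20. Of the called lists beside cholesterol genes, the members lower among males, females, mice of 13.9 weeks and younger mice numbered 3, 5, 4 and 6 of the E-box targets, 11, 12, 12 and 12 of the fatty acid genes, 4, 6, 3 and 4 of the acute phase genes, 12, 7, 9 and 8 of the Kupffer markers and 7, 2, 3 and 3 of the endothelial markers, and of the REV-ERB-repressed genes 4, 4, 5 and 3 were higher. The libraries of 1 time alone gave 943 at ZT0, 1156 at ZT4, 75 at ZT16 and 6 at ZT20.

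Without ZT16 and ZT20, the counts were 797 at ZT0, 1353 at ZT4, 2158 at ZT8, 2887 at ZT12, 454 for an effect that differs between times, 2113 and 94 for the rhythm in wild type and knockout, 468 for a differing rhythm, 1295 for sex in wild type and 23 for a sex difference that differs. The GC correction gave 3447 rhythmic genes in knockout, and 3881 for any difference between the 6 times. With wild-type ZT16 replicate 3 left out as well, it gave 3497, 449 for a differing rhythm, 1392 for sex in wild type and 51 for a sex difference that differs. DESeq2 gave 493 for an effect that differs between times, 500 for a differing rhythm, 824 for sex in wild type and 61 for a sex difference that differs, and no filter gave 35 for the last. An estimated correlation left 1 of 7 lists, the REV-ERB-repressed genes, and fry called 11.

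With 1 of the 36 libraries left out, counts ranged from 4416 to 5235 over all times, 94 to 335 at ZT0, 222 to 580 at ZT4, 656 to 1370 at ZT8, 932 to 1867 at ZT12, 652 to 2542 at ZT16, 200 to 644 at ZT20, 180 to 372 for an effect that differs between times, 6458 to 7542 and 5326 to 6806 for the rhythm in wild type and knockout, 246 to 392 for a differing rhythm, 239 to 1191 and 438 to 1158 for sex in wild type and knockout, 7 to 40 for a sex difference that differs, and 6 to 7 lists.

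Of 436 results of genes that the naming rule selects, 113 lost a call under at least 1 alternative, 42 of them when 1 library was left out, and 3 reversed. Cela1 over all times went from 0.91 to -0.32 in the libraries labelled female alone, wild-type ZT16 replicate 3 among them. Xist at ZT16 went from 8.82 to -0.068 without wild-type ZT16 replicate 3, and to -0.17 with the GC trend removed too. Dmbt1 in knockout went from 8.23 to -1.23 without knockout ZT16 replicate 3. Depth limits what was seen of genes with few reads: 8453 of 21654 were not tested.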

Other observations

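Tests chosen after the data were seen were those of body weight and age.

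Stress and growth genes moved singly in knockout. Of 18 genes of the unfolded protein and integrated stress response, 1 was higher and 5 lower, with the transcription factor gene Atf5 at a log2 fold change of 1.3 ± 0.12 (SE, n = 18), Atf4 at -0.27 ± 0.06 and asparagine synthetase, Asns, at -2.29 ± 0.41, a call that ended without wild-type ZT12 replicate 1 (adjusted p = 0.076). Without knockout ZT4 replicate 2, 8 were lower, and without any 1 of wild-type ZT0 replicate 1, ZT12 replicate 2, ZT16 replicate 2, 2 were higher. Of 14 systemic cue genes of heat shock and cold response, 2 were higher and 1 lower, with the small heat shock gene Hspb1 at -2.29 ± 0.16 and the cold-induced Rbm3 and Cirbp at 0.43 ± 0.09 and 0.45 ± 0.10. Of 11 immediate early genes, 1 was higher and 5 lower (1 and 6 adjusted over the list alone), with Junb at -0.71 ± 0.18 and Zfp36 at -0.67 ± 0.18. Of 12 genes of the growth hormone and IGF axis, 3 were higher and 3 lower, with Stat5b, which carries the growth hormone signal, at 0.48 ± 0.06, Igfals at -0.51 ± 0.11 and Onecut1 at -1.26 ± 0.34. Of 14 cell cycle genes, 4 were higher and 5 lower, with Cdkn1a at 3.75 ± 0.30, Ccnd1 at -1.69 ± 0.27 and Rrm2 at -1.14 ± 0.13. Camera called none of these 5 lists, with adjusted p values of 0.70, 0.84, 0.18, 0.84 and 0.84, and 0.90 for each with an estimated correlation. The cell cycle list had a median of -0.10 and a mean of 0.04, and the systemic cue list 0.06 and -0.03, where camera's direction was down in both.

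Markers of other cells were mostly lower or did not pass the test. Of 10 neutrophil and lymphocyte markers, 5 were lower and 0 higher (7 and 1 adjusted over the list alone), with the T cell gene Cd3g at -1.22 ± 0.29 and the granzyme gene Gzma at -2.07 ± 0.44; 3 were lower without either of wild-type ZT0 replicate 2, ZT12 replicate 2, and 2 were higher without wild-type ZT16 replicate 1. Of 14 interferon response genes, 8 were lower and 1 higher (9 and 1 adjusted over the list alone), with Psmb8 at -0.60 ± 0.10 and Rsad2 at 1.05 ± 0.13; 5 were lower without wild-type ZT20 replicate 1, and 2 were higher without wild-type ZT16 replicate 1. Of 13 stellate cell and fibrosis markers, 4 were lower, with Lrat at -0.78 ± 0.15 and Des at -0.53 ± 0.14. Of 9 bile duct markers, 1 was higher and 2 lower, with Sox9 at 1.35 ± 0.15. Of 7 blood markers, 1 was higher and 1 lower, and the call of the lower, Alas2, ended without any 1 of 15 libraries (adjusted p = 0.050 to 0.12), namely wild-type ZT0 replicates 2 and 3, ZT4 replicate 3, ZT8 replicate 2, ZT12 replicates 1 and 2, ZT16 replicate 3, ZT20 replicate 2, and knockout ZT0 replicate 3, ZT4 replicates 2 and 3, ZT8 replicate 2, ZT12 replicate 1, ZT16 replicate 2, ZT20 replicate 3. Of 5 adipocyte markers, 2 were lower and 0 higher (2 and 1 adjusted over the list alone), with Cidec at -1.16 ± 0.27; 1 was higher without any 1 of 8 libraries, namely wild-type ZT4 replicate 3, ZT12 replicate 1, ZT20 replicate 1, and knockout ZT0 replicate 2, ZT4 replicate 1, ZT8 replicate 1, ZT12 replicate 2, ZT20 replicate 2, and 2 without wild-type ZT16 replicate 1. Of 2 pancreatic acinar markers tested, 1 was higher, Cela1 at 0.91 ± 0.27, and the list was too short for camera. Camera adjusted p values for the 6 others, in the order given, were 0.14, 0.19, 0.18, 0.84, 0.75 and 0.84, and 0.90 for each with an estimated correlation. The adipocyte list had a median of 0.22 and a mean of -0.11. Of 24 female-biased genes, 3 were higher and 10 lower in knockout (3 and 12 adjusted over the list alone), and of 26 male-biased genes, 4 and 8 (5 and 8), with adjusted p values of 0.35 and 0.84, and 0.90 and 0.95 with an estimated correlation. The male-biased list had a median of -0.40 and a mean of 0.05, and a median of 0.25 without wild-type ZT16 replicate 3, with 9 higher and 5 lower. Without wild-type ZT12 replicate 1 or ZT20 replicate 2, 5 were lower too. For the lists of this part with no other count given, the counts adjusted over the list alone were the same.

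Knockout females weighed less than wild-type females. Their mean weight was 19.2 ± 2.94 g against 22.4 ± 1.37 g (SD, n = 9; exact two-sided permutation test over 48620 splits, p = 0.0053, Benjamini-Hochberg 0.021 over 4 tests). Males weighed 23.5 ± 2.39 g in knockout and 24.9 ± 2.38 g in wild type (exact permutation p = 0.23, adjusted 0.43), and whether the sexes differ in this was not tested. Age gave an exact permutation p of 0.33 in males (adjusted 0.43) and 1 in females. The wild-type females include wild-type ZT16 replicate 3, the library with 4 reads of Xist.

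A knockout made in cells of another mouse strain can leave DNA of that strain around the target, which might bring changed genes close to Arntl. Of 119 tested genes within 10 Mb of Arntl on chromosome 7, 9 were called and at least 2-fold changed, a share of 7.56% against 5.20% of all genes tested. Of 12086 windows of the same size around other genes, 16.7% had as high a share, so the share near Arntl was not unusual. A share over 10 Mb on each side can neither show nor exclude a shorter block. Of the 9 genes, Mical2, Micalcl and Tead1 lay closest to Arntl, at mm9 positions 119369370 to 120050319. Their log2 fold changes were 1.10, 2.22 and -1.09.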
